A study of Mus musculus with 2 samples.

How the data were processed

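Heart tissue of female B6CASTF1/J mice aged 18 to 20 months was profiled by long-read RNA sequencing in 1 group of 2 libraries, with 2 µg of RNA for each library per the labels. The labels list a separate biological sample for each library and the same donor entry for both. The deposited tables hold raw counts of long reads per transcript model, per the file headers, with each model's gene, its class relative to the annotation, its number of exons and its length. The deposited transcript models give the coordinates of every exon. The notes deposited with each library state alignment to mm10 with the GENCODE M21 annotation, and the deposited models name TALON as their source. The aligner, program versions, read filters and model filters are not given in the sources used here. Per the deposited files each library was annotated and counted on its own. Rows at 0 reads are not listed, so a gene without a row was taken as having no listed reads in that library, and folds against 0 reads were bounded at a floor of 3 reads.

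New models carry different names in the 2 deposited files, so they were matched here. Known transcripts were matched by identifier, new models of 2 or more exons by their chain of introns, new single-exon models by a reciprocal overlap of at least 50%, and unannotated loci by overlap on 1 strand. Of 95358 models in either library 25898 were found in both, and 936 of these carried a different class in the 2 libraries. The spliced structure of every model was checked against its listed number of exons, with 0 differences among 58180 and 63076 models. Reads of ERCC control RNAs, those antisense to a control included, were counted apart from mouse reads. Gene coordinates are those of the annotation.

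Listed reads numbered 642970 in replicate 1 and 677209 in replicate 2, of which 630211 and 664319 were mouse reads. Annotated genes with at least 5 reads numbered 7422 and 7864. Library sizes were scaled by TMM factors (0.986 and 1.014) computed with edgeR 4.0.16 in R 4.3.3, and CPM and all ratios were computed here. At this depth, in data simulated at the observed read numbers with counting error only, 33 of 100 genes with a 2-fold difference and 70 of 100 with a 4-fold difference were called. With at least 100 reads it was 19 of 21 and 21 of 21, while 3 of 7345 unchanged genes were called. The simulation left out any spread between libraries beyond counting error, so the 3 calls are no error rate for these data.

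Differences between the libraries were tested per annotated gene with at least 10 reads over both libraries, by an exact two-sided binomial test against the scaled library sizes. Leading transcript shares were tested by Fisher's exact test in genes with at least 10 reads in each library, the genomic class left out. Both were adjusted by the Benjamini-Hochberg method and called at 0.05. The tests compare 2 libraries of 1 group and not conditions. Intervals are exact Clopper-Pearson 95% intervals. The common biological coefficient of variation came from edgeR with an intercept only, as a description. For each gene list with at least 3 tested members, the median log2 ratio (0.5 reads added to each library) was placed among the medians of 10000 random lists of the same size drawn from 20 expression bins. DESeq2 1.42.0 gave size factors for an alternative. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

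The other procedures were tested on simulated data as well. Fisher's exact test called 194 of 200 genes of 100 reads whose leading share was lowered by 30 points and 3 of 200 unchanged ones. Of 200 unchanged lists, made of independent genes simulated with counting error only, 9 fell outside the middle 95% of random lists. Simulated coefficients of variation of 0.1 and 0.2 were recovered as 0.0979 and 0.202.

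The results, tests, 36 gene lists, the list of 60 genes with known splice variants, most alternatives and the rule for named genes were chosen before the data were examined. That rule named the 20 genes with the highest mean CPM (mitochondrially encoded genes apart), and for each list its up to 5 most abundant members, every called member, and members without reads in lists that serve as checks. It also named the 10 genes with the largest ratio in each direction among called genes with at least 50 reads, and the splice-variant genes with at least 20 reads in each library. The 10 called genes with the largest difference in leading share, the 10 new-splice models with the most reads and the 5 most abundant unannotated loci (at least 5 reads in each library) completed it. A few genes that the rule names are not reported here. Gapdh, mt-Atp8, Cdkn2a and Gdf15 were named after their values were seen. So were Scp2 and the 5 gene lists composed after the differing genes were seen, namely airway epithelium, lipogenesis, glucocorticoid response, endoplasmic reticulum chaperones and plasma cell and immunoglobulin.

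Alternatives changed the normalization (total counts, DESeq2 size factors, mitochondrially encoded genes left out), the minimum of reads, the transcript classes counted (known only, genomic class or incomplete matches left out), depth (the deeper library thinned), list members and replicates. Added after the data were seen were merged unannotated loci as genes, erythroid genes left out before scaling, new single-exon models left out, Pln left out, and 3 more settings for the coefficient of variation. The test of genes was planned over all genes. Unannotated loci were taken out of it, because the way they were split differed between the libraries, and their inclusion after merging is given as an alternative. Sums of touching genes on the same strand, within 100 bases, were also computed after the data were seen. Variants of the CAST parent against the reference and the SIRV controls named in the labels were not analysed here.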

Results

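Long-read RNA sequencing, in which a single read can cover a transcript over much of its length, was used to profile heart tissue of female mice of the hybrid strain B6CASTF1/J at 18 to 20 months of age. The series formed 1 group with 2 libraries, replicate 1 and replicate 2, each started from 2 µg of RNA. The labels list a separate biological sample for each library but name the same donor entry for both, so whether 1 animal or more than 1 was used is not given in the sources used here. Every SD therefore measures only the spread between 2 samples of 1 group, which may in part be technical, and the tests set the difference between these 2 samples against counting error only. Replicate 1 had 630211 reads assigned to mouse transcript models and replicate 2 had 664319, so that 1 read equalled 1.61 CPM (reads per 1000000 TMM-scaled mouse reads) in replicate 1 and 1.48 CPM in replicate 2. Values after ± are SDs over the 2 libraries (n = 2) throughout, and bracketed ranges are exact 95% intervals that cover counting error only. With 1 group there was no contrast between conditions. The questions were which genes and transcript forms the aged heart expressed, and how closely the libraries matched.

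Genes of mitochondrial energy supply, contraction and oxygen carriage led the expressed genes. Slc25a4, the adenine nucleotide carrier of the inner mitochondrial membrane (chromosome 8, 46206797 to 46211284, mm10), was the most abundant gene at 29468 ± 289 CPM. By mean CPM it was followed by Cox4i1, a cytochrome c oxidase subunit, at 15152 ± 651 CPM. Pln, phospholamban, the regulator of the sarcoplasmic reticulum calcium pump, came next at 14855 ± 609 CPM. In replicate 1 alone Hba-a1, at 16653 CPM, lay above Cox4i1 and Pln. Myh6, the alpha myosin heavy chain, stood at 13715 ± 1158 CPM, Atp5b, the beta subunit of ATP synthase, at 13083 ± 884 CPM, Ndufa4, a respiratory chain subunit, at 12916 ± 473 CPM, and Fabp3, the heart fatty acid binding protein, at 12336 ± 77.3 CPM. Also among the 20 most abundant nuclear genes were Hba-a1, Tnnc1, Tpm1, Cox6a2, Uqcrq, Mb, Myl3, Ckm, Hbb-bs, Hrc, Myl2 and Fxyd1, from 11563 ± 7199 CPM for Hba-a1 down to 4766 ± 273 CPM for Fxyd1. Together the 20 genes took 20.5% ± 1.09 of the mouse reads, and the 100 most abundant nuclear genes took 40.0% ± 1.30.

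Among gene groups chosen before the data were examined, the nuclear-encoded respiratory chain was the largest by summed level, with 123119 ± 1303 CPM over 26 genes. These levels are numbers of reads, and whether genes with long transcripts were under-counted was not tested. The sarcomere group summed to 61120.2 ± 3193 CPM over 24 genes, led by Myh6, Tnnc1 (9835 ± 1116 CPM), Tpm1 (9114 ± 632 CPM), Myl3 (7066 ± 403 CPM) and Myl2 (4991 ± 431 CPM). Fatty acid oxidation summed to 31179 ± 1121 CPM over 23 genes, with Fabp3, Lpl, the lipoprotein lipase (3569 ± 242 CPM), Hadhb (2755 ± 298 CPM), Etfb (1685 ± 57.8 CPM) and Acadm (1541 ± 83.5 CPM) at the top. The 16 genes of glycolysis and glucose uptake summed to 14604 ± 349.8 CPM, led by Aldoa (3732 ± 110.4 CPM), Ldhb, Eno3, Ldha and Pgam2. The 18 citric acid cycle genes summed to 17627 ± 114 CPM, with Sdhb, Idh2, Mdh1 and Mdh2 among the most abundant. Calcium handling genes summed to 28964.5 ± 1244 CPM over 16 genes, with Pln, Hrc (5178 ± 40.8 CPM), Atp2a2, the sarcoplasmic reticulum calcium pump (4686 ± 471 CPM), S100a1 (1360 ± 129 CPM) and Srl (873 ± 58.5 CPM). With reads of known transcripts only this sum was 10860.1 CPM, as Pln kept 793 and 862 reads. Ion channels and gap junctions were far lower at 1056 ± 13.3 CPM over 16 genes, led by Gja1, connexin 43 by its usual protein name, at 509 ± 17.1 CPM, with Kcnj11, Kcnip2 and Kcnh2 also among the most abundant. Gapdh, looked at after its value was seen, had only 13 and 12 reads in the 2 libraries, and its value and those of other genes with near-identical pseudogene copies, ribosomal protein genes among them, are uncertain because reads of such copies can be split or set aside in counting.

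Mitochondrially encoded mRNAs summed to 12019.9 ± 144 CPM, or 18242.7 CPM with reads of known transcripts only. The second value is higher because its base is the smaller number of scaled reads of known transcripts. The most abundant were mt-Cytb (5875 ± 47.9 CPM), mt-Co1 (2699 ± 199.9 CPM), mt-Nd2 (818 ± 26.0 CPM), mt-Nd1 (754 ± 42.1 CPM) and mt-Atp6 (630.1 ± 3.21 CPM), and mt-Atp8 had no listed reads. By annotation, protein-coding genes outside the mitochondrial chromosome held 90.9% ± 0.212 of the mouse reads, the mitochondrial chromosome 1.25% ± 0.00674 and processed pseudogenes 1.54% ± 0.0378. A total of 11355 annotated genes had reads in both libraries, out of 15031 in either, and 6752 had at least 5 reads in each. With unannotated loci added, 15383 genes were seen in both libraries.

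Transcripts of other cell types of the heart were present at lower levels. Fibroblast genes summed to 3010 ± 298 CPM, of which Gsn, the actin-severing protein gelsolin, gave 2255 ± 195 CPM, with Dcn, Col3a1, Mgp and Serping1 next. Endothelial genes summed to 1505 ± 279 CPM, or 856 CPM with reads of known transcripts only (Fabp4, Eng, Egfl7, Gpihbp1 and Esam the most abundant), macrophage and monocyte genes to 437.5 ± 90.8 CPM (Lyz2, C1qc, C1qa, C1qb and Pf4), and mural cell genes to 345 ± 9.89 CPM (Rgs5, Acta2, Tagln, Abcc9 and Kcnj8). Mesothelial and epicardial genes summed to 99.5 ± 29.3 CPM, or 40.6 CPM with reads of known transcripts only (C3, Upk3b, Gpm6a, Msln and Lrrn4). Schwann cell and neuron genes gave 22.2 ± 6.38 CPM (12.7 CPM with reads of known transcripts only), led by Dbh, Uchl1, Kcna1 and S100b, and no member had enough reads to be tested. Neutrophil genes had 4 reads in replicate 1, of S100a8 and Retnlg, and none in replicate 2. The 4 Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had no listed reads in these female samples, which allows up to 3 reads for each gene in each library. Xist, the RNA that coats the inactive X chromosome, had 4 and 7 reads, none of them of known transcripts. Skeletal muscle genes summed to 45.6 ± 25.8 CPM, mostly of Myl1, Mybpc2, Atp2a1, Casq1 and Mylpf, and Myh4, Myh2, Tnnt3 and Pvalb had no listed reads.

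Transcription factors of the heart muscle summed to 2732 ± 387 CPM (364 CPM with reads of known transcripts only), most of it from Esrra, the estrogen-related receptor alpha, at 2243 ± 321 CPM. The level of Esrra is uncertain, because all but 23 and 21 of its 1535 and 1358 reads were of the genomic class, reads that overlap a gene without following its splice sites. Nkx2-5 (106 ± 19.1 CPM), Gata4, Srf and Mef2a followed. Splicing regulators summed to 863 ± 24.2 CPM (483 CPM with reads of known transcripts only), led by Qk (192 ± 6.57 CPM), Rbm24, Hnrnpu, Mbnl2 and Rbpms. Long non-coding RNAs summed to 378 ± 38.5 CPM, with Hand2os1 at 99.2 ± 12.9 CPM, Mhrt, the antisense transcript of the myosin heavy chain locus, at 88.9 ± 1.80 CPM, then Neat1, Gas5 and Malat1. Imprinted genes summed to 279 ± 6.09 CPM, of which Snrpn gave 144 ± 8.21 CPM, followed by Igf2r, Cdkn1c, Sgce and Impact. Senescence genes gave 65.5 ± 6.09 CPM, led by Cdkn1a, Glb1 and Trp53, with Cdkn2b at 1 read in each library, and Cdkn2a and Gdf15 had no listed reads. Immediate early genes gave 195 ± 1.32 CPM (Dusp1, Ier2, Jun, Junb and Zfp36), circadian clock genes 169 ± 16.5 CPM (Nr1d1, Tef, Arntl, Bhlhe40 and Cry1), interferon response genes 168 ± 51.5 CPM (Ifi27l2a, Gbp2, Bst2 and Rtp4 among them) and the 19 ribosomal protein genes 5817 ± 104 CPM (Rpl5, Rplp0, Rpl13, Rps9 and Rpl4).

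Between the libraries, globin genes were higher in replicate 1, while genes of atrial muscle and of fat cells were higher in replicate 2. Hba-a1, an alpha chain of hemoglobin, was 2.57-fold [2.48 to 2.67] higher in replicate 1, and Hbb-bs, a beta chain, 2.63-fold [2.49 to 2.77]. Nppa, the atrial natriuretic peptide, was 2.22-fold [2.02 to 2.45] higher in replicate 2, as were Myl4, the atrial essential light chain of myosin, at 2.70-fold [2.35 to 3.11] and Cfd, adipsin, a protein secreted by fat cells, at 13.1-fold [8.49 to 21.2]. Bpifa1, a secreted protein of airway epithelium, had 294 reads in replicate 2 and none in replicate 1, a difference of at least 90.4-fold against the floor of 3 reads. The great majority of genes lay close together in the plot of gene levels in the 2 libraries.

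**Figure D1:**
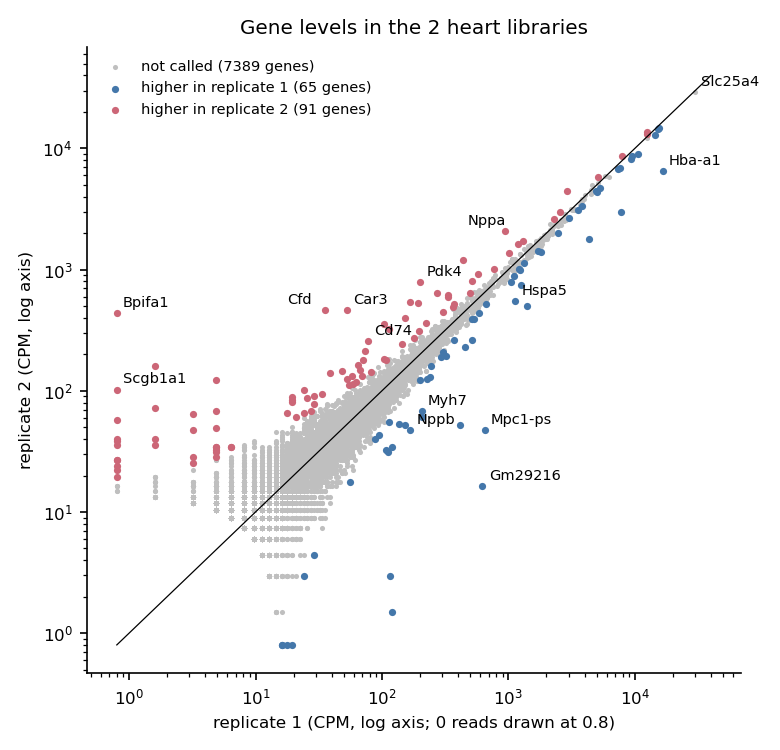
Levels of the 7545 tested genes in replicate 1 (x axis) and replicate 2 (y axis), both in CPM on log axes; each dot is a gene, colours mark the 65 genes higher in replicate 1 and the 91 higher in replicate 2, and the line marks equal levels. Bpifa1 and Scgb1a1 had no reads in replicate 1, and Hba-a1 lies below the line at 2.57-fold.

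An exact two-sided binomial test on the reads of each gene, which compares these 2 libraries and not conditions, called 156 of 7545 tested genes after Benjamini-Hochberg adjustment, 65 higher in replicate 1 and 91 higher in replicate 2. That is 2.07% of the tested genes, and 90 of the 156 differed at least 2-fold. With library sizes taken from total counts instead of TMM factors, the split was 51 and 106, counting only reads of known transcripts gave 38 and 64, and testing only genes with at least 50 reads gave 84 and 77, so that which library held more called genes depended on the setting. Across genes, which are not independent replicates, Pearson's r of log2 reads was 0.919 and Spearman's rho was 0.887. Of the most abundant genes in no group, Mb, myoglobin, was 1.11-fold [1.07 to 1.16] higher in replicate 1, and Uqcrq, a subunit of respiratory complex III, was 1.09-fold [1.05 to 1.13] higher in replicate 2. The common biological coefficient of variation from edgeR was 0.162. Called folds as small as 1.05 lie below that spread, since the test has no term for it.

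The erythroid group was higher in replicate 1 as a whole. All 5 tested members passed the test, and all 5 when adjusted over the list alone. Beside Hba-a1 and Hbb-bs these were Hba-a2 at 2.47-fold [2.30 to 2.64], Hbb-bt at 2.78-fold [2.45 to 3.16] and Alas2, the erythroid enzyme of heme synthesis, at 2.56-fold [1.71 to 3.89]. The summed level was 30391 CPM in replicate 1 and 11784 CPM in replicate 2, a 2.58-fold ratio. Reads of the near-identical pair Hba-a1 and Hba-a2, and of the pair Hbb-bs and Hbb-bt, cannot be divided with certainty, so the sum is the firmer value. The median log2 ratio of replicate 1 over replicate 2 was 1.36, at percentile 100 among 10000 random lists matched on expression.

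Called atrial genes were at least 2-fold higher in replicate 2, while called ventricular genes were higher in replicate 1 by smaller folds. In the atrial group, 4 of 10 tested members were higher in replicate 2 over all genes tested, and 7 when adjusted over the list alone. These 4 were Nppa, Myl4, Myl7, the atrial regulatory light chain, at 2.34-fold [1.95 to 2.81] and Sln, sarcolipin, an atrial inhibitor of the calcium pump, at 2.63-fold [2.08 to 3.36]. Clu, the next most abundant member, was not called, at 160 and 180 reads. The group median was a log2 ratio of −1.04, at percentile 0. In the ventricular group, 3 of 4 tested members were higher in replicate 1 (3 adjusted over the list alone): Myl2, the ventricular regulatory light chain, at 1.13-fold [1.08 to 1.19], Myl3 at 1.08-fold [1.04 to 1.13] and Fhl2 at 1.31-fold [1.17 to 1.48]. Irx4 had 16 and 7 reads and was not called, and Hey2 had no listed reads. The median was 0.28, at percentile 98.4, or 0.20, at percentile 94.6, with reads of known transcripts only. Myl3 had 4568 reads in each library, so its call rests on the library sizes alone. It lost its call with total counts as library sizes, and Myl3 and Fhl2 lost theirs with reads of known transcripts only.

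Genes used as markers of cardiac stress did not move together. Nppb, the B-type natriuretic peptide, was 3.52-fold [2.35 to 5.41] higher in replicate 1 and Myh7, the beta myosin heavy chain, 3.02-fold [2.14 to 4.32], whereas Nppa and Ankrd1, the cardiac ankyrin repeat protein, at 1.63-fold [1.32 to 2.03], were higher in replicate 2, although Ankrd1 lost its call with reads of known transcripts only (log2 ratio −0.64 instead of −0.70). Of 7 tested members 2 were thus called in each direction, and 3 in each when adjusted over the list alone. Acta1 and Acta2 were not called, at 416 ± 80.5 and 72.1 ± 11.8 CPM. The median log2 ratio was 0.33, at percentile 99.6, and with reads of known transcripts only it was 0.17, at percentile 92.3. With all reads the median was the value of Acta2, which was not called. The summed level went the other way, at 2118 CPM in replicate 1 and 3052 CPM in replicate 2, with Nppa the most abundant member. In the sarcomere group 7 of 23 tested genes were higher in replicate 1 and 1 in replicate 2 (8 and 1 adjusted over the list alone). Those in replicate 1 included Myh6 (1.13-fold [1.09 to 1.16]), Tnnc1 (1.17-fold [1.13 to 1.22]), Tpm1 (1.10-fold [1.06 to 1.14]), Myl2, Myl3 and Myh7. Tcap, the titin cap protein, was 1.55-fold [1.46 to 1.64] higher in replicate 2. The sarcomere median was 0.12, at percentile 96.5.

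Few calcium handling and heart transcription factor genes differed. Pln was 1.06-fold [1.03 to 1.09] and Atp2a2 1.15-fold [1.10 to 1.21] higher in replicate 1. These were 2 of 15 tested members, with 5 higher in replicate 1 and 1 in replicate 2 when adjusted over the list alone, a median of 0.08 and percentile 73.2. The difference of Pln did not pass with total counts as library sizes, and its log2 ratio turned to −3.49 with the genomic class left out, which held most of its reads in replicate 1. Esrra was 1.23-fold [1.14 to 1.32] and Gata4, a zinc finger factor of heart muscle, 2.21-fold [1.37 to 3.64] higher in replicate 1, and Ppara, a nuclear receptor for fatty acids, had 11 reads against none, at least 3.98-fold. These were 3 of 16 tested transcription factors, and 3 adjusted over the list alone, with a median of 0.27 at percentile 97.3. With reads of known transcripts only, Esrra and Gata4 were no longer called, and Ppara had no reads of known transcripts.

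Metabolic genes were close between the libraries apart from a few members and a small shift of most fatty acid oxidation genes towards replicate 2. Pdk4, the kinase that inhibits pyruvate dehydrogenase, was 3.92-fold [3.22 to 4.80] higher in replicate 2, and Hadhb, the beta subunit of the mitochondrial trifunctional protein, 1.17-fold [1.09 to 1.25]. They were 2 of 23 tested genes of fatty acid oxidation, while 1 was called in replicate 1 and 3 in replicate 2 when adjusted over the list alone. Of the 23 genes 20 had a higher share of reads in replicate 2, and the group median was a log2 ratio of −0.13, at percentile 0.05. In glycolysis and glucose uptake, Hk2, a hexokinase, was 1.54-fold [1.22 to 1.95] higher in replicate 1 as the 1 called gene of 16 (2 adjusted over the list alone, median 0.06, percentile 61.1), and its call was lost with reads of known transcripts only. Of 26 respiratory chain genes, Cox4i1 (1.06-fold [1.03 to 1.09]) and Cox6a2 (1.15-fold [1.11 to 1.19]) were higher in replicate 1, and Atp5b (1.10-fold [1.07 to 1.13]) and Ndufa4 (1.05-fold [1.02 to 1.09]) in replicate 2, the same 2 and 2 counts as when adjusted over the list alone, with a median of 0.04 at percentile 40.5. Cox4i1 was not called with total counts as library sizes, Atp5b was not called with reads of known transcripts only, and Ndufa4 then had a log2 ratio of 0.06. None of the 18 citric acid cycle genes was called, over all genes or adjusted over the list alone (median −0.05, percentile 3.61). None of 10 mitochondrially encoded mRNAs was called over all genes and 1, higher in replicate 1, adjusted over the list alone (median 0.04, percentile 44.8).

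Fat cell genes were higher in replicate 2. Of 10 tested adipocyte genes 8 were called, all in replicate 2, and all 10 when adjusted over the list alone. Beside Cfd, these included Car3, a carbonic anhydrase abundant in fat, at 8.67-fold [6.04 to 12.8], Cidea, a lipid droplet protein of brown fat, at 2.81-fold [2.14 to 3.72], Cidec, a lipid droplet protein, at 10.2-fold [3.18 to 51.7], and Adipoq, adiponectin, with 1 and 27 reads, a ratio of 24.9 [4.11 to 1020]. Ucp1, the uncoupling protein of brown fat (7.07-fold [2.14 to 36.8]), Retn, resistin (6.76-fold [2.03 to 35.3]), and Pck1 (1 and 24 reads, 22.1-fold [3.61 to 910.4]) completed the called genes. The summed level was 227 CPM in replicate 1 and 1477 CPM in replicate 2. The median log2 ratio was −3.12, or −2.86 with members at 0 reads set to 3 reads, at percentile 0.

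Antigen presentation genes were also higher in replicate 2. Cd74, the invariant chain of MHC class II, was 3.33-fold [2.40 to 4.68] and H2-Ab1, a class II beta chain, 4.38-fold [2.33 to 8.97] higher. These were 2 of 4 tested class II genes, with all 4 called when adjusted over the list alone and a median of −1.91 at percentile 0. H2-Aa and H2-Eb1 had 5 and 23, and 4 and 17 reads. In the macrophage and monocyte group Lyz2, lysozyme, was the 1 called gene of 13, at 1.77-fold [1.30 to 2.44] in replicate 2, and also the 1 gene called when adjusted over the list alone (median −0.52, percentile 0.715, which was 16.0 with reads of known transcripts only and 3.84 with the most abundant member left out). In the lymphocyte group Jchain, the joining chain of secreted antibodies, had no reads in replicate 1 and 24 in replicate 2, at least 7.38-fold. It was 1 of 2 tested members, with both called when adjusted over the list alone. Cd79a had 1 and 13 reads, Ighm 1 and 8 and Cd79b 1 and 3. The list summed to 52.4 ± 58.2 CPM, and the median of its 2 tested members was −4.28, or −2.97 with 0 reads set to 3 reads.

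Stromal and vascular groups differed at few genes. Col3a1, a fibrillar collagen chain, was 1.91-fold [1.31 to 2.82] higher in replicate 2, the 1 called gene of 13 tested fibroblast genes (2 adjusted over the list alone, median −0.28, percentile 2.40, which was 4.13 with reads of known transcripts only and 2.60 with the most abundant member left out). Its call was lost with the deeper library thinned to the same total of mouse reads, at a log2 ratio of −0.83 instead of −0.92. Fabp4, a fatty acid binding protein of capillary endothelium and fat, was 1.60-fold [1.40 to 1.83] and Gpihbp1, the endothelial anchor of lipoprotein lipase, 1.89-fold [1.28 to 2.85] higher in replicate 2, as 2 of 16 tested endothelial genes (3 adjusted over the list alone, median 0.04, percentile 55.4). Both lost their calls with reads of known transcripts only, at log2 ratios of −0.70 instead of −0.68 for Fabp4 and −0.87 instead of −0.91 for Gpihbp1. Ifi27l2a was 2.28-fold [1.53 to 3.46] higher in replicate 2, the 1 called gene of 4 tested interferon response genes (1 adjusted over the list alone, median −0.21, percentile 25.2).

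Among checks for neighbouring tissues, lung and liver genes had reads mainly in replicate 2. Scgb1a1, a secretory protein of club cells, had 69 reads in replicate 2 and none in replicate 1, at least 21.2-fold, and Sftpa1, a surfactant protein, had 16 and none, at least 4.92-fold. Both tested lung genes were thus called, also when adjusted over the list alone, but Sftpc, Sftpb and Cldn18 had no listed reads. Cyp2e1 had 26 reads in replicate 2 and none in replicate 1, at least 7.99-fold, and Ahsg, fetuin, had 3 and 21, a ratio of 6.46 [1.93 to 33.8]. Both tested liver genes were called, also when adjusted over the list alone, while Alb, Fgb and Fga had no listed reads. Neither of the 2 tested skeletal muscle genes was called over all genes, and Myl1, with 5 and 24 reads, was the 1 called when adjusted over the list alone.

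No member was called over all genes in the remaining groups. These were ion channels and gap junctions (12 tested, median −0.03, percentile 44.4), splicing regulators (14 tested, 0.05, percentile 61.4), mural cells (9 tested, 0.06, percentile 62.2), mesothelial and epicardial cells (4 tested, −0.59, percentile 5.61), senescence (4 tested, −0.20, percentile 34.2), immediate early genes (8 tested, −0.38, percentile 9.33), the circadian clock (10 tested, −0.36, percentile 12.8), ribosomal proteins (19 tested, −0.10, percentile 1.59, which was 7.39 with reads of known transcripts only and 15.2 with the most abundant member left out), imprinted genes (7 tested, 0.12, percentile 65.1), long non-coding RNAs (5 tested, −0.26, percentile 7.32) and Xist. When adjusted over the list alone, 1 of these genes was called, a long non-coding RNA higher in replicate 2. Of the lists fixed before the data were examined that had at least 4 tested members, 10 had medians outside the middle 95% of random lists, as drawn in the plot of gene lists, and 5 with reads of known transcripts only.

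**Figure D2:**
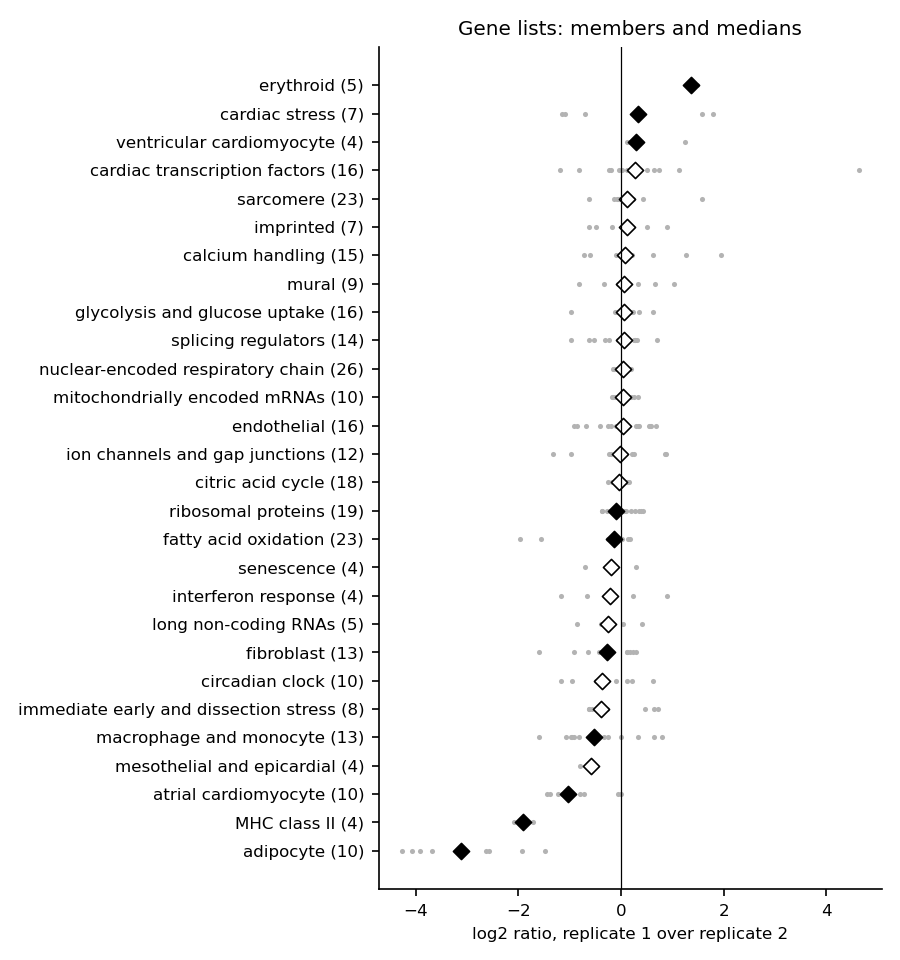
Log2 ratio of CPM, replicate 1 over replicate 2 (x axis), for the tested members of each list (grey dots; number in brackets) and their median (diamond; filled for the 10 lists outside the middle 95% of 10000 random lists matched on expression). The erythroid median lies at 1.36 and the adipocyte median at −3.12.

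The genes with the largest ratios in replicate 2 were Bpifa1, Scgb1a1, Scgb3a1, a secretoglobin of airways with 1 and 108 reads (99.6-fold [17.5 to 3971]), Fasn, fatty acid synthase, with 1 and 49 reads (45.2-fold [7.74 to 1821]), Oaz1-ps, Cfd, Car3, Lrrc10, a leucine-rich repeat protein of heart muscle, at 4.61-fold [2.46 to 9.42], H2-Ab1 and Rhobtb1 at 4.24-fold [2.40 to 7.99]. The difference of Rhobtb1 lay in the genomic class, as it had 8 and 8 reads with that class left out. In replicate 1 they included Nppb, Podn, the proteoglycan podocan, at 3.54-fold [2.19 to 5.91], G0s2, an inhibitor of triglyceride lipase, at 3.44-fold [2.40 to 5.01], and Rrad, a Ras-related protein that limits calcium channels, at 3.30-fold [2.01 to 5.61]. The others were A530058N18Rik, which overlaps Actc1 on the opposite strand (8.02-fold [5.62 to 11.8], with all of its 259 and 35 reads in the genomic class and so uncertain), the lincRNA AC154200.1 (74 and 1 reads) and the pseudogenes Gm29216 (387 and 11), Gm15432 (72 and 2), Mpc1-ps (404 and 32) and Gm6055 (70 and 21). For AC154200.1, Oaz1-ps and these 4 pseudogenes the difference was one of assignment: with the reads of the same-strand gene or unannotated model that they touch added, a check chosen after the data were seen, the ratios were 1.01 [0.728 to 1.39] for AC154200.1 and Oaz1-ps together, 0.939 [0.817 to 1.08] for Gm29216, 1.13 [0.802 to 1.60] for Gm15432, 1.05 [0.914 to 1.21] for Mpc1-ps and 1.15 [0.81 to 1.64] for Gm6055. Podn overlaps Scp2 on the same strand, and their summed reads had a ratio of 0.933 [0.798 to 1.09], so its difference is uncertain too, the more so as all but 2 and 3 of its reads were of the genomic class.

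Most reads of the heart matched annotated transcripts. Known transcripts held 65.9% ± 1.07 of the mouse reads, incomplete matches (reads that cover only part of a known transcript, many of them with 1 exon) 16.1% ± 1.60, and the genomic class (reads that run past exons without matching splice sites) 8.44% ± 0.744. New combinations of known splice sites held 2.62% ± 0.00588 (2.62% [2.58 to 2.66] and 2.63% [2.59 to 2.67]) and models with new splice sites 2.18% ± 0.0564, together 4.80% ± 0.0505. Antisense models held 3.81% ± 0.242 and intergenic models 0.98% ± 0.0145. With new single-exon models left out, a setting chosen after the data were seen, these shares were 0.110% and 0.095%. The 2 libraries differed by more than counting error in known transcripts, 66.6% [66.5 to 66.8] and 65.1% [65.02 to 65.25], in antisense models, 3.64% [3.60 to 3.69] and 3.99% [3.94 to 4.03], in new splice sites, 2.22% [2.18 to 2.25] and 2.14% [2.10 to 2.17], in incomplete matches, 14.9% [14.85 to 15.03] and 17.2% [17.1 to 17.3], and in the genomic class, 8.97% [8.90 to 9.04] and 7.92% [7.85 to 7.98]. Pln alone had 8696 reads in the genomic class and 2 in incomplete matches in replicate 1, but none and 8851 in replicate 2. Without Pln, a setting chosen after this was seen, the incomplete-match shares were 15.2% and 16.1% and the genomic shares 7.71% and 8.03%.

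**Figure D3:**
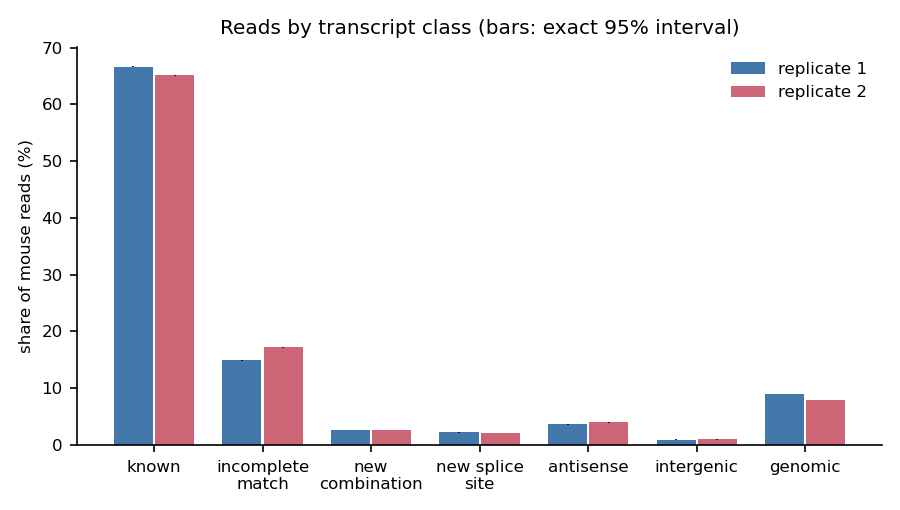
Share of mouse reads (%, y axis) by transcript class (x axis) in replicate 1 (blue) and replicate 2 (red), with exact 95% intervals as lines that are mostly narrower than the line width. Known transcripts hold 66.6% and 65.1%, and the incomplete-match and genomic classes differ in opposite directions.

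Of known transcripts seen in either library, 63.5% [62.8 to 64.3] were seen in both (10662 of 16779). The share was 16.5% [16.1 to 17.0] for the new-splice models, 3938 of 23826, and it was 22.2% for new combinations and 12.6% for new splice sites. Of these models 488 had at least 5 reads in each library. The most abundant belonged to Oaz1, ornithine decarboxylase antizyme (chromosome 10, 80826656 to 80829284, 5 exons), where a new combination held 95.6% ± 0.691 of the gene's reads. Other genes led by a new model were Mpc1, a subunit of the mitochondrial pyruvate carrier (95.6% ± 0.82), Mrpl33, a mitochondrial ribosomal protein (95.5% ± 0.736), Vdac3 (83.8% ± 2.19) and Idh3g (83.5% ± 1.18). The list also held Idh3b (71.6% ± 5.83) and Srl (59.9% ± 1.10). In Myh6, 2 new combinations of 39 exons held 12.2% ± 0.0895 and 3.57% ± 0.0901 of the reads.

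Unannotated loci were mostly classed as antisense to known genes. Of these, 548 had at least 5 reads in each library. The most abundant ran opposite the lincRNA Gm26917 on chromosome 17 (39843013 to 39848035, minus strand) at 999 ± 66.8 CPM. The next lay opposite Klhl31 on chromosome 9 (77656520 to 77657534, minus strand; 869.5 ± 85.7 CPM), Tmem250-ps on chromosome 2 (26136917 to 26138383, plus strand; 774.5 ± 28.9 CPM), Dhrs3 on chromosome 4 (144892910 to 144893585, minus strand; 728 ± 95.04 CPM) and Cdv3 on chromosome 9 (103354312 to 103355313, plus strand; 587 ± 11.7 CPM). The other 4 had only models of 1 exon. The first had models of up to 2 exons, but how many of its reads were spliced was not counted. Which RNA its reads came from was not examined either, so it is not shown to be a separate gene. The strand of reads without splice junctions rests on library preparation steps that are not given in the sources used here. Whether these loci are antisense is therefore uncertain, and so it is for other loci of 1 exon, which held most reads classed as antisense.

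Leading transcripts of heart muscle genes held from 97.1% (Tpm4) down to 6% (Ktn1) of a gene's reads. Tpm1-205 held 94.3% ± 0.426 of the reads of Tpm1, alpha tropomyosin, and Slc25a3-206 held 85.3% ± 0.165 of those of Slc25a3, the mitochondrial phosphate carrier. Pkm-202 held 80.2% ± 2.17 of the reads of pyruvate kinase Pkm against 4.81% ± 2.15 for Pkm-201, and Atp2a2-202 held 72.2% ± 0.589 of those of Atp2a2. Myh6-201 held 33.1% ± 1.73 of the reads of Myh6, followed by a new combination at 12.2% ± 0.102 and Myh6-205 at 10.2% ± 0.257. Vegfa, the vascular growth factor, used Vegfa-207 at 49.5% ± 10.8 and Vegfa-202 at 37.2% ± 15.9, and Rcan1 used Rcan1-201 at 61.1% ± 10.2 and Rcan1-202 at 36.5% ± 8.71. The order of the 2 Vegfa transcripts changed between the libraries. Vegfa-202 had 45 reads against 39 in replicate 1, and Vegfa-207 had 44 against 20 in replicate 2.

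Of 60 genes with known splice variants chosen before the data were examined, 38 had at least 20 reads in each library, and their median leading share was 51.6% ± 2.15. A known transcript led in 22 of them: Tpm4 (97.1% ± 4.16), Cltb (93.6% ± 3.81), Tmod1 (88.8% ± 5.41), Capzb (81.1% ± 7.37), Ldb3 (62.1% ± 1.99), Acsl1 (55.2% ± 5.17), Asph (53.4% ± 2.49), Tpm3 (50.7% ± 4.40), Actn2 (50.2% ± 3.93), Myh7 (49.6% ± 1.19), Kcnip2 (49.2% ± 5.89), Trdn (47.9% ± 0.389), Vldlr (45.2% ± 0.321), Myl6 (44.1% ± 4.13), Cast (24.1% ± 3.57), Tpm1, Slc25a3, Pkm, Atp2a2, Myh6, Vegfa and Rcan1. A new-splice model led in 8, among them Mbnl2 (86.2% ± 4.05), Pdlim5 (69.5% ± 5.47) and Slmap (39.3% ± 5.81), with Camk2d, Sorbs2 and Ktn1 at 18.98% ± 6.65 or less. An incomplete match led in the other 8: Fhod3 (69.1% ± 5.35), Lmna (61.7% ± 2.12), Ttn (45.9% ± 26.8), Tnnt2 (32.8% ± 1.40), Tnni3 (31.2% ± 0.618), Lmo7 (18.6% ± 5.18), Ryr2 (16.0% ± 1.72) and Mybpc3 (10.1% ± 1.49). These shares depend on which classes are counted. Where the leading model is of a class left out, another transcript takes the lead, as in Tnni3 and Tnnt2. The values of these 2 genes below are therefore not shares of the same transcript. With incomplete matches left out the leading share was 49.4% for Myh6 and 40.0% for Tnni3, and with known transcripts only it was 73.6% and 76.9%, while that of Tnnt2 was 16.4% with incomplete matches left out.

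**Figure D4:**
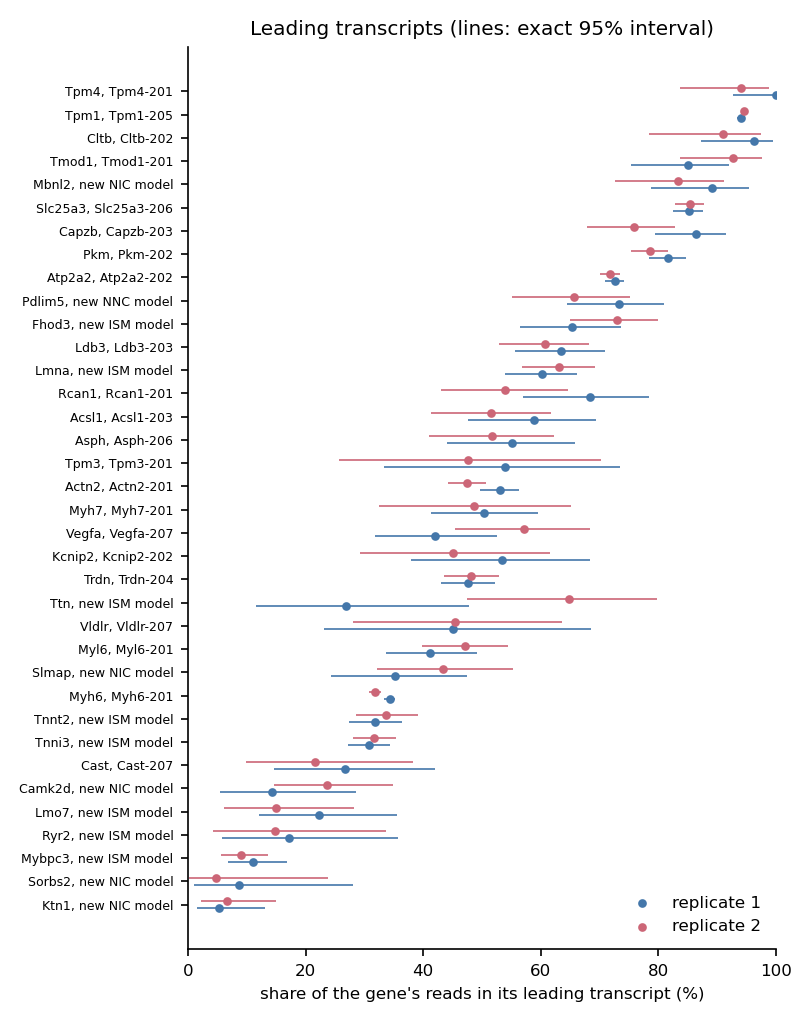
Share of a gene's reads in its leading transcript (%, x axis) for genes of the splice-variant list with at least 20 reads in each library (y axis; not every gene is drawn), in replicate 1 (blue) and replicate 2 (red), with exact 95% intervals as lines. The intervals of Tpm1 sit near 94.3%, and those of Ttn are the widest apart, at 26.9% and 64.9%.

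Fisher's exact test found no list gene with a different leading share between the libraries. Ttn, the giant sarcomere protein titin, had the largest difference, 26.9% [11.6 to 47.8] and 64.9% [47.5 to 79.8], with an adjusted p of 0.328 in Fisher's exact test, on 26 and 37 reads. Over all 3934 testable genes, 87.9% of which were led by a known transcript, 32 were called and 218 had an unadjusted p under 0.05. The 10 largest were Lrg1, Cep19, Vac14, Ndufaf7, Klhl22, Dcun1d5, Tmed9, Cavin2, Cdc34 and Pln, in each of which a single-exon incomplete match took most reads of 1 library, as in Ndufaf7 with none of 149 and 122 of 156 reads. With new single-exon models left out, a setting chosen after this was seen, 0 of 3780 genes were called and 132 had an unadjusted p under 0.05, and none was called with incomplete matches left out or with known transcripts only.

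Genes with the longest transcripts had the lowest share of known transcripts. The median length of the assigned models, each read counted once, was 946 bases in replicate 1 and 1036 in replicate 2 (991 ± 63.6), and 1228 ± 29.0 over known transcripts. In genes whose longest detected known transcript was under 1000 bases, known transcripts held 81.8% ± 1.19 of reads and incomplete matches with the genomic class 16.1% ± 1.19. From 6000 bases on, these shares were 50.5% ± 1.12 and 35.0% ± 1.81. The 4 bins between did not fall evenly, with known shares of 69.4%, 65.6%, 66.4% and 62.2%. Myh6 and Myh7, with leading transcripts of 6113 and 6135 bases, were still led by full known models, while the leading models of Ttn and Ryr2 were incomplete matches of 3690 and 3589 bases.

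Added control RNAs of the ERCC set gave 1.98% [1.95 to 2.02] of listed reads in replicate 1 and 1.90% [1.87 to 1.94] in replicate 2. Of 96 controls, 43 and 48 were seen. The 30 controls with enough reads were tested one by one against the totals of control reads in the 2 libraries. None differed in this exact binomial test with adjustment, and 2 had an unadjusted p under 0.05. Such a test cannot show a shift of all controls together. Relative to scaled mouse reads the controls were 1.07-fold higher in replicate 1, a log2 ratio of 0.10. The labels also name SIRV controls, which were not analysed here.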

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

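Merged unannotated loci, erythroid genes left out before scaling, new single-exon models left out, Pln left out and, for the coefficient of variation, the genomic class or mitochondrial genes left out and the deeper library thinned were chosen only after the results were seen, and the other alternatives before the data were examined. No paired analysis was possible because the series holds only 1 group and no groups were compared.

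The number of genes detected in both libraries depended most on the minimum of reads. Of 15383 genes with at least 1 read in each library, 7300 had at least 5 in each. With 1 library left out the number of detected genes ranged from 23349 to 25605, which counts genes seen in the remaining library alone.

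The coefficient of variation of 0.162 was 0.164 with no filter on low counts, 0.161 with at least 50 reads, 0.167 with known transcripts only, 0.163 with total counts, 0.182 with merged unannotated loci added, 0.189 with the genomic class left out, 0.163 with mitochondrial genes left out, 0.162 with the deeper library thinned and 0.158 with erythroid genes left out.

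The count of 156 differing genes depended on which reads were counted. With known transcripts only it was 102, of which 94 were shared with the 156, and 38 instead of 65 were higher in replicate 1. With the genomic class left out it was 216 (136 shared), and with at least 50 reads 161 (125 shared), of which 84 were higher in replicate 1 and 77 in replicate 2. Total counts as library sizes gave 157 (142 shared), DESeq2 size factors 156 (156 shared), the deeper library thinned 160 (148 shared), erythroid genes left out 150 and merged unannotated loci 193. The log2 ratio of replicate 1 over replicate 2 turned for Rhobtb1 to 0.10 with known transcripts only and 0.11 with the genomic class left out, for Ndufa4 to 0.063 with known transcripts only, and for Pln to −0.020 with known transcripts only and −3.49 with the genomic class left out. The Pln value with the genomic class left out follows from its classes, since its genomic reads were 8696 in replicate 1 and 0 in replicate 2. Rhobtb1 kept 5 and 5 reads of known transcripts, and 8 and 8 with the genomic class left out, so its value there is that of equal reads. The cause was not tested for Ndufa4.

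With known transcripts only, Rhobtb1, Ndufa4 and Pln, with turned ratios, lost their calls, and so did 11 more named genes, with log2 ratios as follows, in brackets those with all reads: Txnip −1.41 (−1.41), Fabp4 −0.70 (−0.68), Gpihbp1 −0.87 (−0.91), Ankrd1 −0.64 (−0.70), Cbr2 −2.02 (−2.27), Hk2 0.50 (0.62), Atp5b −0.11 (−0.14), Myl3 0.09 (0.12), Gata4 0.84 (1.13), Fhl2 0.24 (0.39) and Esrra 0.10 (0.29). Ahsg, Fasn, Ighg2c, Podn, Ppara, Sftpa1, A530058N18Rik and AC154200.1 were among the genes left with under 10 such reads and were not tested. With the genomic class left out Hk2 (0.52), Gpihbp1 (−0.82), Ankrd1 (−0.50), Esrra (0.24) and Rhobtb1 lost theirs, and A530058N18Rik, AC154200.1, Ighg2c, Podn and Ppara had under 10 reads. With erythroid genes left out Ndufa4 lost its call (adjusted p of 0.0506 in the exact binomial test). With total counts Cox4i1, Pln and Myl3 lost theirs, with the deeper library thinned Col3a1 and Ndufa4, and with no minimum of reads Gata4, Gpihbp1, Sdf2l1, Col3a1, Ndufa4 and Txnip.

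Of the summed list levels, 22 moved by more than their SD with known transcripts only, among them heart transcription factors (2732 to 364 CPM) and calcium handling (28964.5 to 10860.1 CPM), and 13 did not. The base of CPM changed too, to the scaled reads of known transcripts, so these counts mix a change of reads with a change of base.

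Of the 10 fixed lists outside the middle 95% of random lists, 5 remained so with known transcripts only (5 shared). With the most abundant member of each list left out 7 remained, and fibroblast (percentile 2.60), macrophage (3.84) and ribosomal protein (15.2) medians came to lie inside. The erythroid, atrial, adipocyte, MHC class II and fatty acid oxidation medians stayed outside in each alternative run on them, while cardiac stress, ventricular, fibroblast, macrophage and ribosomal protein medians did not with known transcripts only.

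The share of reads in known transcripts, 65.9%, was 72.0% with the genomic class left out of the denominator, 73.6% over transcripts with at least 2 reads in each library and 82.0% with new single-exon models left out. The new-splice share of 4.80% was 5.24% with the genomic class left out, 4.86% with mitochondrial genes left out, 2.92% with at least 2 reads in each library, 4.87% without Pln and 5.97% with new single-exon models left out. Of new-splice models with at least 2 reads in either library, 33.9% had at least 2 in each, against 16.5% seen in both among all such models. The base changed with the threshold, and the share for known transcripts was not computed at that threshold.

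The median leading share of the splice-variant genes, 51.6%, was 81.9% with known transcripts only (20 genes) and 67.4% with incomplete matches left out (33 genes), and 50.1% to 53.2% with either library left out. In genes whose leading model was of a class left out, the leading transcript changed too. Fisher's exact test called 32 genes for a different leading share, 29 with at least 30 reads in each library (24 shared), and 0 with incomplete matches left out, 0 with known transcripts only and 0 with new single-exon models left out. The last setting had 132 genes at an unadjusted p under 0.05. The median length of 991 bases was 1228 with known transcripts only, and the spike-in share rose to 2.12% with the genomic class left out of the denominator. Depth limits small differences most. In data simulated at the observed reads with counting error only, 33 of 100 genes with a 2-fold difference were called and 70 of 100 with a 4-fold difference.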

Other observations

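The 5 gene lists described first were composed only after it was seen which genes differed, and the tests of atrial and fat tissue, ventricular stress, blood and Pln classes were chosen only after their results were seen, while those of depth, short transcripts and broken RNA were not.

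Genes of the airway lining had reads almost only in replicate 2. Beside Bpifa1, Scgb1a1 and Scgb3a1 these were Scgb3a2 (0 and 39 reads), Reg3g (0 and 27), Cyp2f2 (0 and 18) and Cbr2 (4 and 23). Of 8 tested genes 7 were higher in replicate 2, also 7 when adjusted over the list alone, and Tppp3 had 9 reads in each library. The list summed to 24.1 CPM in replicate 1 and 894 CPM in replicate 2, with a median log2 ratio of −5.86, or −3.32 with 0 reads set to 3 reads, at percentile 0. Some genes of fatty acid synthesis were also higher in replicate 2: Fasn, Acly (4.15-fold [2.19 to 8.53]), Slc25a1 (2 and 32 reads), Thrsp (2.75-fold [2.23 to 3.41]) and Agpat2 (2.20-fold [1.52 to 3.23]), 5 of 13 tested genes (7 adjusted over the list alone, median −1.13, percentile 0). The fat cell list moved the same way, at 227 and 1477 CPM with 10 of 10 tested members higher in share in replicate 2. The 5 lists composed later were built after the differing genes were seen. Their percentiles and their counts adjusted over the list alone are therefore no independent evidence. The airway list shares Scgb1a1 with the lung list, and the lipogenesis list shares Scd1 with the adipocyte list.

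Of genes known to respond to glucocorticoids, those higher in replicate 2 were Pdk4, Cebpb (3.26-fold [2.61 to 4.09]), Tsc22d3 (2.89-fold [2.06 to 4.12]), Klf15 (3.01-fold [1.98 to 4.70]) and Txnip (2.71-fold [1.48 to 5.23]). Txnip lost its call with known transcripts only and with no minimum of reads. These were 5 of 17 tested genes, and 13 when adjusted over the list alone, with a median of −1.36 at percentile 0. The list shares Pdk4, Dusp1 and Per1 with other lists. Of 18 tested chaperones of the endoplasmic reticulum, 3 were higher in replicate 1, namely Hspa5 (2.05-fold [1.81 to 2.34]), Manf (2.91-fold [1.96 to 4.42]) and Sdf2l1 (18 and 3 reads), and 5 adjusted over the list alone (median 0.59, percentile 100). Of the plasma cell and immunoglobulin list, Jchain and Ighg2c (3 and 23 reads, or 3 and 6 with the genomic class left out) were 2 called of 3 tested genes, higher in replicate 2 (3 adjusted over the list alone, median −4.41, or −2.63 with 0 reads set to 3 reads, percentile 0.015). That list shares Jchain, Ighm and Igkc with the lymphocyte list. No explanation was tested for these 5 lists.

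The first pattern is that atrial and fat cell genes were higher in replicate 2, with 12 called members. For greater depth of the replicate 2 library, 12 of the 12 stayed called with the deeper library thinned. Thinning took replicate 2 only from 664319 to 630211 mouse reads, and the test already scales for library size. Calls of this size could hardly be lost that way, so the step says little about depth. A ventricular stress response that raises Nppa together with Nppb and Myh7 is argued against only in that form. Nppb and Myh7 had log2 ratios of 1.80 and 1.58 towards replicate 1, values known before the test was chosen. Of the 7 tested stress genes 3 had a higher share of reads in replicate 2, Nppa and the called Ankrd1 among them. A stress response of another form was not decided. More atrial and fat tissue in the replicate 2 library stays open and was not decided. Of the tested members of the 2 lists that were not called, 8 of 8 had a higher share of reads in replicate 2 (median log2 ratio −0.90), but an earlier form of this test with the called members had already shown 10 of 10 in each list, so its outcome was known. Of the 12 atrial genes 3 are in other lists (Nppa, Kcnj3 and Gja5), 9 of the 11 fat cell genes had reads in both libraries, and how the tissue was dissected is not given in the sources used here.

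The second pattern is that the 5 tested erythroid genes were higher in replicate 1. A preference of the replicate 1 library for short transcripts is argued against, as 183 other genes with leading transcripts of 554 to 703 bases had a median log2 ratio of 0.054 against 1.36. More blood in the replicate 1 library stays open and was not decided: the 95% intervals of 5 of the 5 genes held the ratio of the summed list, 2.58, but the sum is made of the same genes. No biological explanation is given by the design, which has 1 group, and none was tested.

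The third pattern is that incomplete matches were higher and the genomic class lower in replicate 2. Most of it went with Pln reads given different classes in the 2 libraries: without Pln the difference in incomplete matches was 0.944 percentage points instead of 2.27, and the genomic share, 7.71% and 8.03%, was no longer lower in replicate 2. More broken RNA or shortened cDNA in the replicate 2 library was not decided. Among reads of models with 2 or more exons the difference was 0.934 points (12.8% and 13.8%), smaller than 2.27. That step also takes out the single-exon incomplete match of Pln, with 8846 reads in replicate 2, and changes the denominator. The smaller value therefore does not speak against broken RNA. The smaller difference in incomplete matches that was left stays open. No biological explanation was tested.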
